A study of Mus musculus with 36 samples.

How the data were processed

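Gene expression was measured in 36 samples of Bhas 42 cells, a mouse fibroblast line derived from BALB/c 3T3 cells that carries a viral Ha-ras oncogene and is used in cell transformation assays. Per the labels, cells were treated from day 4 after seeding and collected on day 6, after 48 h of exposure. The 9 groups held 4 samples each: water (2%), the synthetic amorphous silica NM-203 at 1, 2 and 5 µg/cm², diatomaceous earth (DE) at 5 µg/cm², the crystalline silica Min-U-Sil 5 at 20 µg/cm² with a water control of its own, the phorbol ester TPA at 0.05 µg/ml, and its solvent DMSO (0.1%). The series record speaks of 4 independent experiments, but no label ties an array to one of them. The limma p-values of genes thus measure only the spread between these samples. The number of arrays limits the precision of every value.

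Each sample was hybridised to one 1-colour Agilent array with Cy3-labelled cRNA, per the labels. Per the file headers, the authors extracted the spot intensity with Agilent Feature Extraction 11.0.1.1, which subtracted background and corrected spatial trends but did not normalize between arrays. The processed intensity, the flags for control, outlier, saturated and well-above-background spots, and the median spot and background intensity were used. The files held no mean spot intensity, so the alternative with normexp background correction (offset 50) and quantile normalization used the deposited median intensity. The deposited value table held log2 values of the same arrays, centred on the median of each probe; how the authors scaled the arrays before that is not stated. Its column medians ran from -0.254 to 0.269 over 56745 probes. Each array was set against every column of its group, and the best correlation across probes lay between 0.9993 and 0.9999. For 33 of the 36 arrays the best column was their own. Replicates 1, 2 and 3 of Min-U-Sil 5 each matched the column of another Min-U-Sil 5 replicate, with correlations of 0.406 to 0.68 for their own columns, so the group was unaffected and the scanner files' numbers were kept.

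Each array had 62976 spots, of which 59305 were not controls, on 56605 probes. The files named probes by accession only. Unversioned RefSeq accessions named 32994 probes (22911 genes) through a reference gene table of the assembly GRCm38.p6, and 23611 probes stayed unnamed here. The array design was built on mm9, so no coordinates are given. Between 31189 and 43117 probes per array (55.1% to 76.2%) were well above background, the 75th percentile of the intensity lay between 531 and 1542, and 0 spots were saturated. Spike-in signals followed their amounts with slopes of 0.936 to 1.05. The headers placed the arrays on 5 slides scanned on 2 days: slides 1 to 3 on the first day, slides 4 and 5 on the second.

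The main values were log2 of the processed intensity minus the array's 75th percentile over spots that were not controls. Outlier spots were left out (74 to 380 per array) and spots of one probe were averaged. A probe was tested if it was well above background on at least 3 of 4 arrays in at least 1 group, which 40676 probes were, and the brightest probe stood for each gene name. This gave 32489 gene names, 17868 with a gene symbol and 14621 without, which enter the counts only. All 9 group means were fitted to the 36 arrays at once with limma 3.58.1 (lmFit and eBayes, 27 residual degrees of freedom) in R 4.3.3, with the data.table package (1.17.8). Calls are genes with a Benjamini-Hochberg adjusted p under 0.05. Values after ± are the standard error (SE) of the fit with 4 arrays per group unless named otherwise, and adjusted p-values of genes come from limma. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The tests of the contrasts between effects subtract one treatment's change against its own control from another's.

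Where a probe was not well above background on any array of a group, the fold is given as at least N-fold: the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

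Gene lists were tested with camera (preset correlation 0.01, adjusted over the lists of a comparison), with an estimated correlation and fry beside it. Camera sets the genes of a list against all other genes. At the preset correlation its p-values rest mainly on the spread across genes, not on that between arrays. Very small camera values are therefore not evidence of that strength from 4 arrays per group. The 28 lists were AP-1 and immediate early, ERK pathway output and feedback, NF-kB targets, inflammasome and pyroptosis, interferon stimulated, proliferin family, matrix metalloproteinases and plasminogen system, fibrillar collagen and matrix, smooth muscle and contractile, DNA replication and S phase, G2 and mitosis, p53 targets, NRF2 antioxidant, metallothionein, heat shock, unfolded protein and integrated stress response, cholesterol synthesis, fatty acid synthesis, lysosome and phagosome, scavenger receptors, hypoxia and glycolysis, cell adhesion and gap junction, TGF-beta and BMP response, growth factor and receptor, and the markers of macrophages, epithelium, endothelium and adipocytes. The comparisons, lists, tests, most alternatives and the rule for named genes were chosen before the data were examined. By that rule, per comparison with a control, named genes had an adjusted p under 0.05, all 4 treated arrays on one side of all 4 control arrays, a probe well above background on all 4 arrays of a group, and a gene symbol. The 8 largest rises and 8 largest falls were eligible, plus up to 3 members of each list, or the brightest member where none passed. For direct tests the 5 largest positive and 5 largest negative values were eligible, and a gene named once may be quoted elsewhere. The text names a part of these.

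On simulated data for NM-203 at 5 µg/cm² against water, with 32489 genes of which 200 changed, 13.4% of genes with a log2 change of 0.5 were recovered, 47.8% at 1 and 89.4% at 2. There 2 of 102 calls were false, 0 genes were called in an unchanged comparison, and camera called the 1 list that had been shifted and 0 of the others. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.

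Counts within a slide came from a fit of every combination of group and slide to all 36 arrays. Where a group had 1 array on a slide, the spread thus came from the other arrays, and the lone array was assumed to vary like them. Alternatives were other scalings (quantile, the median of the genes tested, normexp, the deposited table), other filters and probe rules, a signal floor, fits on the groups of a comparison alone, slide, scan day and replicate number as blocks, array weights, other empirical Bayes settings, a rank scale of dose, minimum folds of 1.5 and 2, and leaving out each array. Chosen after seeing the data were fits on the first scan day alone, DMSO or the second water group as a control, a fit without slide 4, the value table's numbering of Min-U-Sil 5, the exact permutation of list levels, and the gene families by name. Chance correlation and covariance between comparisons with a shared control were taken from 100 simulated draws of unchanged groups. Each draw took arrays at random from all 36, less their group means and with random signs, and 4 of them stood as the shared control. The draws gave no chance overlap of calls.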

Results

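Bhas 42 cells were exposed for 48 h to amorphous silica (NM-203), diatomaceous earth (DE), crystalline silica (Min-U-Sil 5) or the tumour promoter TPA, and their RNA was measured on 36 arrays, 4 in each of 9 groups. Replicate arrays correlated with r between 0.953 and 0.993 across genes within groups. In a principal component analysis the first component held 36% of the variance and set apart the 3 Min-U-Sil 5 arrays and 2 of its water controls on slide 4 (117 to 154). The sixth array of that slide, replicate 2 of NM-203 at 2 µg/cm², lay at 54.9, nearer to arrays of slide 5. The second component held 13.5% and was lowest in NM-203 at 5 µg/cm². The number of changed genes ran from 28 for NM-203 at 1 µg/cm² to 10740 for NM-203 at 5 µg/cm².

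**Figure D1:**
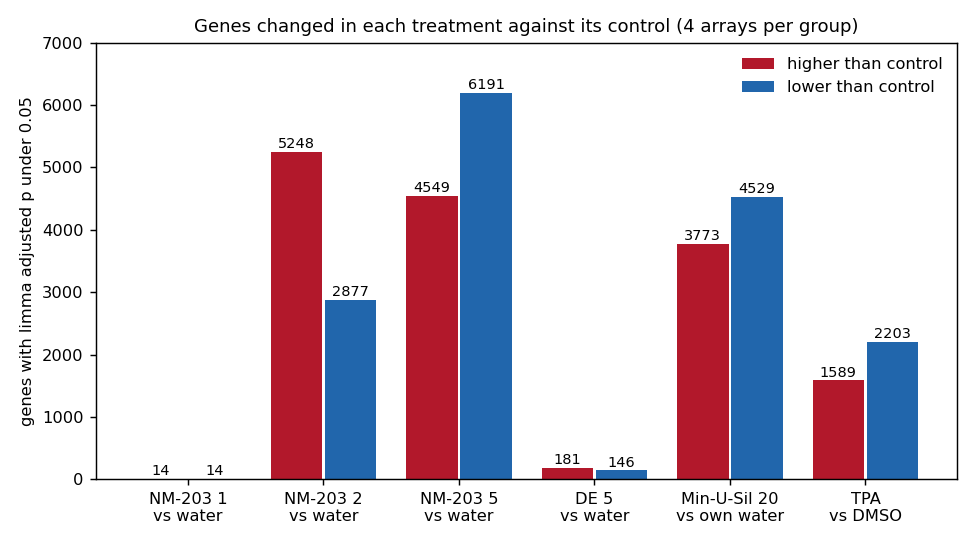
Number of genes with a limma adjusted p under 0.05 in each treatment against its control, split into higher (red) and lower (blue), with 4 arrays per group. NM-203 changed 14 genes each way at 1 µg/cm² and 4549 up and 6191 down at 5 µg/cm², while DE at 5 µg/cm² changed 181 and 146.

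NM-203 at 5 µg/cm², the highest dose of this amorphous silica, was compared with water to see what a high dose changes in these cells. Genes of cell division rose and genes of the extracellular matrix fell. All 43 measured genes of the G2 and mitosis list rose, with a mean log2 change of 2.08, and 38 of 39 genes of the DNA replication and S phase list rose, with a mean of 1.82. Among them the centromere guardian Sgo1 rose 6.12-fold, the spindle checkpoint kinase Bub1 5.66-fold and the replication initiation factor Mcm10 7.72-fold. The acute-phase protein gene Saa3 had the largest rise, 30.2-fold (log2 change 4.92 ± 0.27, n = 4 per group, limma adjusted p = 3.39e-14). The proliferins Prl2c3, Prl2c1 and Prl2c5, prolactin-like hormones, rose 24.1-fold, 20.0-fold and 18.4-fold, although probes of such near-identical genes can share signal, so their separate values are uncertain. The secreted carbonic anhydrase Car6 rose 18.2-fold (adjusted p = 6.52e-15) and Nlrp2 11.4-fold. Large falls were seen in the organic anion transporter Slco2b1, at least 17.5-fold lower (adjusted p = 4.55e-16), Sparcl1, 23.0-fold lower (adjusted p = 1.87e-17), and S100b, 19.3-fold lower.

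The matrix lists fell together in this group. Of 29 measured fibrillar collagen and matrix genes 21 fell and 0 rose past the limma threshold, with a mean log2 change of -1.08 (camera adjusted p = 4.76e-14): periostin (Postn) was 11.1-fold lower, lumican (Lum) 9.01-fold lower and Col6a3 3.41-fold lower. Of 20 matrix metalloproteinase and plasminogen genes 12 fell and 2 rose, with a mean of -0.83 (adjusted p = 0.000145), Mmp3 by 11.3-fold and Mmp9 by 8.72-fold. The growth factor and receptor list also fell, 13 of 28 members lower and 1 higher with a mean of -0.43 (adjusted p = 0.00304), including Gas6 and Igf2 (log2 changes of -2.47 and -1.99), while the hormone Fgf21 rose 9.86-fold. Interferon stimulated genes rose, 25 of 27 with a mean of 1.24 (adjusted p = 2.27e-17): Oasl1 10.4-fold, the antiviral Rsad2 8.09-fold and the chemokine Cxcl10 6.68-fold. The unfolded protein and integrated stress response list rose in 20 of 33 members with a mean of 0.68 (adjusted p = 7.88e-08), led by the cystine transporter Slc7a11 (6.89-fold) and by Shmt2 and Psat1, enzymes of serine and one-carbon metabolism (4.01-fold and 3.98-fold). The heat shock list rose in 11 of 17 members and fell in 1, with a mean of 0.57 (adjusted p = 7.42e-06), with the chaperone genes Hsph1 2.60-fold and Hspd1 2.12-fold higher. These calls, with those of both cell cycle lists (adjusted p = 3.73e-38 and 3.04e-33) and the proliferin family (3 of 3, mean 4.37, adjusted p = 1.28e-08), held with an estimated correlation.

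Another 5 lists passed camera but not with an estimated correlation. NF-kB targets rose with a mean of 0.74, 11 of 25 higher and 5 lower, among them the cyclooxygenase gene Ptgs2, 6.81-fold higher (adjusted p = 0.00367, adjusted p = 0.214 with an estimated correlation). NRF2 antioxidant genes rose with a mean of 0.33, 16 of 33 higher and 2 lower (adjusted p = 0.000907, adjusted p = 0.129 with an estimated correlation), with the glutathione synthesis gene Gclc 2.78-fold higher and the aldehyde oxidase Aox1 3.24-fold lower. ERK pathway output rose with a mean of 0.44, 9 of 21 higher and 4 lower (adjusted p = 0.0426, adjusted p = 0.344 with an estimated correlation), including the ERK phosphatase Dusp4 (7.12-fold), Fosl1 (5.05-fold) and Hbegf (3.54-fold). Lysosome and phagosome genes fell with a mean of -0.29, 18 of 39 lower and 3 higher, Lamp2 by 1.83-fold (adjusted p = 0.00152, adjusted p = 0.393 with an estimated correlation). Cell adhesion genes fell with a mean of -0.32, 11 of 25 lower and 5 higher (adjusted p = 0.0128, adjusted p = 0.166 with an estimated correlation), with Ncam1 3.35-fold lower and the gap junction gene Gja1 2.80-fold higher.

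The other 14 lists did not pass camera after NM-203 at 5 µg/cm². Of 24 AP-1 genes 7 rose and 2 fell (adjusted p = 0.113), Myc by 5.70-fold among the risen. Of 34 hypoxia and glycolysis genes 11 rose and 8 fell (adjusted p = 0.165), of 27 p53 targets 5 and 11 (adjusted p = 0.541), of 26 TGF-beta genes 4 and 9 (adjusted p = 0.152), and of 14 scavenger receptors 2 and 6 (adjusted p = 0.151). Of 12 inflammasome genes 3 rose and 4 fell (adjusted p = 0.853), of 18 smooth muscle genes 3 and 4 (adjusted p = 0.922), of 25 cholesterol synthesis genes 2 and 2 (adjusted p = 0.541), of 24 fatty acid synthesis genes 2 and 3 (adjusted p = 0.853) and of 5 metallothionein list members 2 and 1 (adjusted p = 0.501). Among markers of other cell types, 3 of 10 macrophage genes fell (adjusted p = 0.387), including Aif1 and Lyz2 by 3.29-fold and 2.82-fold, and 1 of 6 epithelial genes fell, Krt8 by 3.15-fold (adjusted p = 0.694). Of 5 endothelial markers 2 fell (adjusted p = 0.152), Cdh5 by at least 2.88-fold, and of 6 adipocyte markers 0 passed limma (adjusted p = 0.501). The median and mean log2 change had opposite signs for macrophage markers (0.08 and -0.23), epithelial markers (0.22 and -0.10) and smooth muscle genes (-0.05 and 0.01, camera direction down). Adjusted over the list alone, the counts of all lists were those given over all genes tested, except for 1 more inflammasome and 1 more smooth muscle gene higher, 2 more growth factor genes higher, and 1 more p53, NRF2 and TGF-beta gene each lower.

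**Figure D2:**
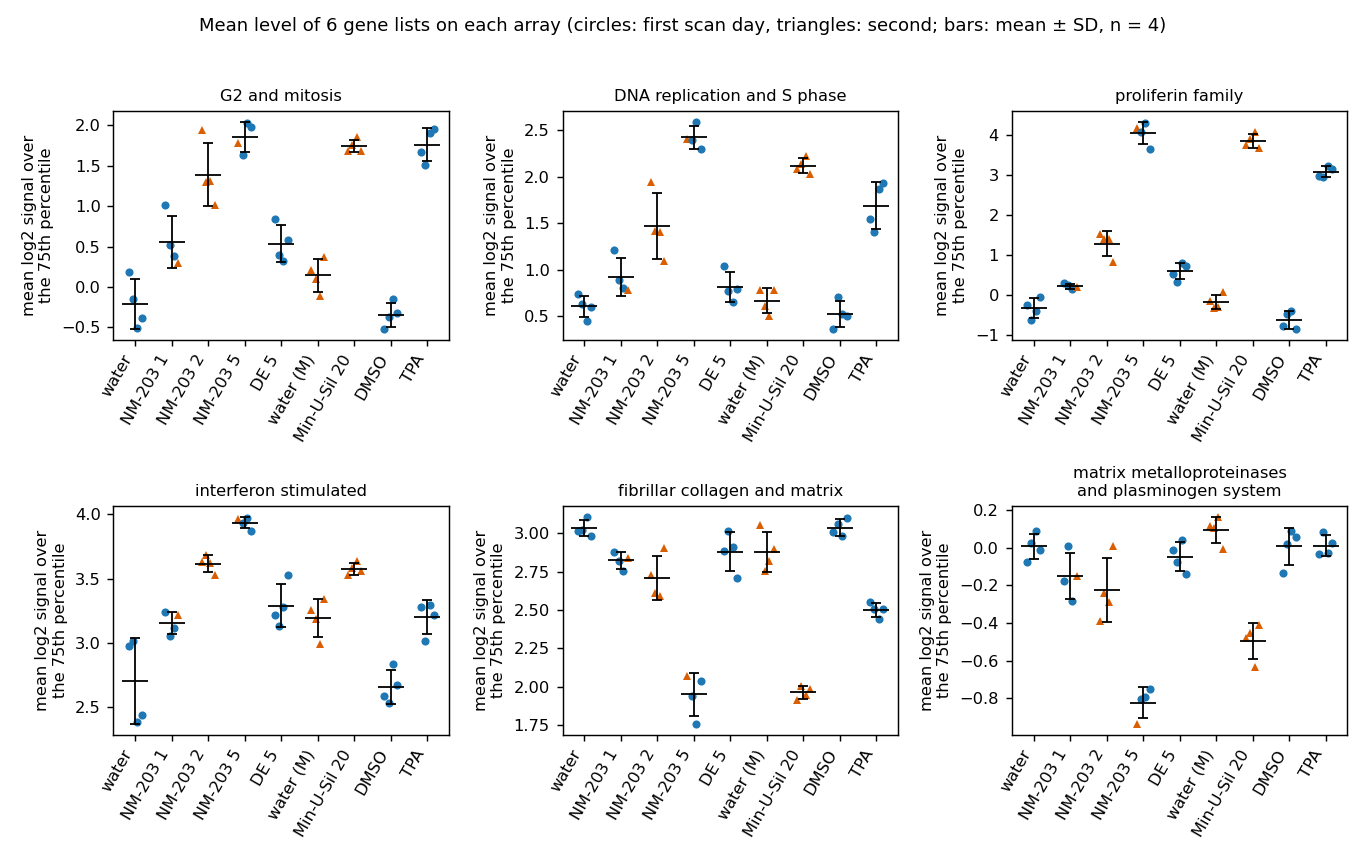
Mean level per array of 6 gene lists (log2 signal over the array's 75th percentile) in the 9 groups, with bars for the mean ± SD of 4 arrays, circles for the first scan day and triangles for the second. The G2 and mitosis list rose from -0.22 in water to 1.86 in NM-203 at 5 µg/cm², from 0.14 in its own water control to 1.75 in Min-U-Sil 5 and from -0.35 in DMSO to 1.76 in TPA, and the collagen list was lowest in NM-203 at 5 µg/cm² (1.95) and Min-U-Sil 5 (1.96).

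The limma test called 10740 of 32489 genes for NM-203 at 5 µg/cm² against water, 4549 higher and 6191 lower, and 3656 at least 2-fold. With the slide as a block 10590 genes were called. Slides 1 and 3 held both groups, with 2 NM-203 arrays and 1 water array and with 1 of each, and gave 5631 and 5027 calls with the spread taken from all arrays. With that block the mean change was 2.22 for the G2 and mitosis list, 1.90 for S phase, 1.32 for interferon stimulated genes, 4.32 for proliferins, -1.10 for the collagen list and -0.85 for the metalloproteinase list. Within slides 1 and 3 these were 2.40 and 2.15, 1.84 and 1.94, 1.49 and 1.55, 4.02 and 4.46, -1.09 and -1.17, and -0.77 and -0.90. Scaled on the median of the genes tested, the median change of all genes was 0.11 and the balance of calls turned to 4416 higher and 4065 lower, so direction counts are relative to the scaling.

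The lower doses of NM-203 were compared with the same water controls to see which changes begin there. At 1 µg/cm² mitotic genes were already higher: 41 of the 43 G2 and mitosis genes rose when adjusted over the list alone, 6 when adjusted over all genes, with a mean log2 change of 0.77 (camera adjusted p = 1.97e-76). The spindle genes Aspm (1.97-fold) and Spag5 (1.86-fold), the mitotic kinases Plk1 (1.78-fold, adjusted p = 0.0447) and Nek2 (1.77-fold) and the kinesin Kif4 (1.78-fold) rose. Car6 rose 2.34-fold (adjusted p = 0.0186) and mesothelin (Msln) 2.03-fold (adjusted p = 0.000762). The falls included the signalling regulator Rgs8, 2.63-fold lower (adjusted p = 0.0447), the cartilage matrix gene Ucma, 2.38-fold lower, the calcium channel gene Cacna1g, 1.96-fold lower (adjusted p = 0.00923), and Tmem158, 1.63-fold lower (adjusted p = 0.000762). Interferon stimulated genes rose as a list with a mean of 0.45 (adjusted p = 8.78e-34), 0 of 27 over all genes and 23 adjusted over the list alone, where Isg15 was 0.43 higher on the log2 scale (adjusted p = 0.437). The proliferin list had a mean of 0.55 (adjusted p = 9.59e-07), with 0 of 3 members over all genes and 3 adjusted over the list alone; Prl2c5 was 0.59 higher (adjusted p = 0.151).

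These 3 lists held with an estimated correlation at 1 µg/cm², and 6 others that passed camera did not. They were S phase (mean 0.32, adjusted p = 1.17e-19, adjusted p = 0.101 with an estimated correlation), cholesterol synthesis (mean 0.23, adjusted p = 8.73e-08, and 0.325), lysosome and phagosome (mean 0.08, adjusted p = 0.0122, and adjusted p = 0.54), collagen and matrix (mean -0.21, adjusted p = 2.8e-07, and 0.084), metalloproteinases (mean -0.16, adjusted p = 0.00496, and 0.0584) and smooth muscle (mean -0.13, adjusted p = 0.047, and 0.429), each second value being the adjusted p with an estimated correlation. Over all genes 0 members of these lists passed limma, and adjusted over the list alone 4 collagen and matrix genes fell and 1 lysosome gene rose. The lysosome list also lost its call with the slide (adjusted p = 0.072) or the scan day (adjusted p = 0.169) as a block. Against DMSO on the first scan day its direction was reversed (mean -0.031, camera adjusted p = 0.662).

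In all, 28 genes changed at 1 µg/cm², 14 higher and 14 lower, and 1864 had an unadjusted p under 0.05. Fitted on the 8 arrays of both groups alone, limma called 0 genes (2673 with an unadjusted p under 0.05), and 100 with the slide as a block. The count was 101 without water replicate 1, 18 without water replicate 2, 2 without water replicate 3, 2 without water replicate 4, and 4, 2 and 4 without NM-203 replicates 1, 2 and 4. Normexp scaling called 38 genes, 36.8% of them higher in place of 50%, and scaling on the median of the genes called 1, which was lower. Each of slides 1, 2 and 3 held 1 NM-203 array, against 1, 2 and 1 water arrays, and gave 10, 17 and 0 calls with the spread taken from all arrays (1301 with an unadjusted p under 0.05 on slide 3), and the mean change of the G2 and mitosis list was 0.77, 1.00 and 1.03, and 0.87 with the slide as a block. Interferon stimulated genes had within-slide means of 0.68, 0.25 and 0.67 and 0.49 with the block, and proliferins 0.20, 0.73 and 0.63 and 0.52 with the block.

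At 2 µg/cm² cell cycle and interferon stimulated genes were higher than in water. Of the 43 G2 and mitosis genes 42 rose (mean 1.61), including Aurkb (4.38-fold), Nek2 (4.16-fold) and Plk1 (4.01-fold), and of 39 S phase genes 33 rose (mean 0.86), including Mcm10 (3.41-fold) and Dtl (3.37-fold). Of 27 interferon stimulated genes 26 rose (mean 0.92), with Oasl1 at 3.56-fold (adjusted p = 1.25e-05) and Irf7, a transcription factor of this response, at 2.74-fold. Car6 rose 5.41-fold (adjusted p = 5.65e-09), Saa3 3.40-fold (adjusted p = 2.05e-05), Prl2c3 3.53-fold, Pid1 5.56-fold and the inflammatory caspases Casp1 and Casp4 2.49-fold and 2.15-fold. Ucma was at least 3.09-fold lower, and Cd247, Postn and Mmp9 fell 5.88-fold, 4.19-fold and 2.34-fold. Txnrd1, a thioredoxin reductase of the NRF2 list, was 2.00-fold lower against water (adjusted p = 1.83e-06) but not against the Min-U-Sil 5 water control scanned on the same day (log2 change 0.03, adjusted p = 0.937). Of the genes selected for naming from those eligible in this comparison, 20 kept their direction and call against that control. Another 9 kept the direction and fell short of the threshold, and Txnrd1 was reversed. Among the 9 were Cd247 (adjusted p = 0.144), Casp1 (adjusted p = 0.0542), Casp4 (adjusted p = 0.135) and Mmp9 (adjusted p = 0.0673).

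The lists past camera at 2 µg/cm² were G2 and mitosis (adjusted p = 2.51e-39), S phase (3.52e-19), interferon stimulated (2.02e-18), proliferins (mean 1.61, 1.39e-05), collagen and matrix (11 of 29 lower and 2 higher, mean -0.32, 2.34e-05), cholesterol synthesis (15 of 25 higher, mean 0.47, 0.000491), metalloproteinases (6 of 20 lower and 1 higher, mean -0.23, 0.0025) and heat shock (10 of 17 higher and 1 lower, mean 0.38, 0.00281). With an estimated correlation 0 lists passed, although 7 had an unadjusted p under 0.05 and fry called 16. The adjusted p with an estimated correlation was 0.0658 for the G2, interferon, proliferin and metalloproteinase lists, 0.127 for S phase, 0.173 for collagen, 0.268 for heat shock and 0.544 for cholesterol synthesis. Adjusted over the list alone, 35 S phase, 12 heat shock and 2 metalloproteinase genes rose, 12 collagen and 7 metalloproteinase genes fell, and the other counts were unchanged. The test called 8125 genes, 5248 higher and 2877 lower, at a median change of 0.11 over all genes, to which these directions are relative. Replicate 2 of this group stood apart on the third principal component (122), with 380 outlier spots, a median spot variation of 13.8% and the lowest array weight (0.199).

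All arrays of NM-203 at 2 µg/cm² were scanned on the second day and all water arrays on the first, and no slide held both, so scan day could be separated from this group only through 1 array each of NM-203 at 1 and 5 µg/cm² on the second day. With the slide as a block 2327 genes were called and with the scan day 1716. Against the Min-U-Sil 5 water control, on the same scan day, 1692 genes were called. The mean change of the G2 and mitosis list was 1.95 and 1.83 with the slide or scan day as a block and 1.25 against that other control. For S phase these values were 1.04, 0.97 and 0.80, for interferon stimulated genes 0.95, 0.86 and 0.42, for proliferins 1.56, 1.54 and 1.46, and for collagen -0.39, -0.42 and -0.17, the last no longer past camera (adjusted p = 0.113). The heat shock list was lost with the slide as a block (mean 0.16, adjusted p = 0.157) and with the scan day as a block (mean 0.16, adjusted p = 0.448).

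A linear slope over 0, 1, 2 and 5 µg/cm² was fitted to the group means of each gene. As 2 µg/cm² is the mean of these doses, its arrays have a weight of 0 in the slope. The slope thus sets 5 µg/cm² against water and 1 µg/cm². A call does not show a steady change over all doses. Saa3 rose by 0.97 ± 0.05 on the log2 scale per µg/cm² (limma adjusted p = 7.89e-15), Prl2c3 by 0.94 ± 0.04 and Car6 by 0.81 ± 0.04. Sparcl1 had a slope of -0.91 ± 0.03 (adjusted p = 3.47e-18), Ptgds, a prostaglandin synthase, of -0.89 ± 0.05, and S100b of -0.89 ± 0.04. The slope was called for 11286 genes, 4844 rising and 6442 falling with dose, and scaled on the median of the genes for 9200, 4761 rising and 4439 falling.

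**Figure D3:**
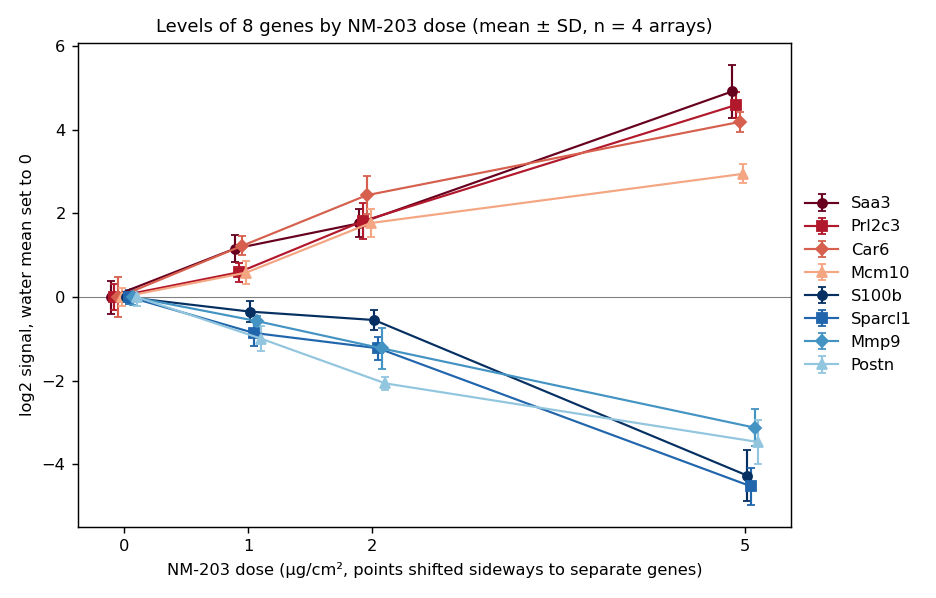
Levels of 8 genes against the NM-203 dose in µg/cm² (log2 signal with the water mean set to 0, mean ± SD of 4 arrays). Saa3, Prl2c3, Car6 and Mcm10 rose and S100b, Sparcl1, Mmp9 and Postn fell, with Saa3 at 4.92 and S100b at -4.27 at 5 µg/cm².

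Diatomaceous earth, a mostly amorphous natural silica, was tested at the same 5 µg/cm² against the same water controls. Saa3 rose 10.8-fold (log2 change 3.43 ± 0.27, limma adjusted p = 9.5e-09) and Car6 3.34-fold (adjusted p = 4.13e-05). Of the 43 G2 and mitosis genes 18 rose, 40 adjusted over the list alone, with a mean log2 change of 0.75 (camera adjusted p = 6.82e-52), including the kinesin Kif2c (2.19-fold) and the checkpoint gene Bub1b (1.98-fold). Of 27 interferon stimulated genes 10 rose, 26 adjusted over the list alone, with a mean of 0.59 (adjusted p = 6.08e-36), including Rsad2 (2.51-fold). All 3 proliferins rose (mean 0.92, adjusted p = 4.7e-10), and of 25 NF-kB targets 4 rose, 6 adjusted over the list alone (mean 0.47, adjusted p = 1.3e-10), including the chemokine Ccl8 (2.58-fold) and lipocalin Lcn2 (2.03-fold). The falls were led by Rgs8 (2.55-fold, adjusted p = 0.0122), Ucma (2.51-fold), Chadl (2.40-fold) and the prostaglandin receptor Ptger1 (2.31-fold). These 4 lists held with an estimated correlation.

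A further 5 lists passed camera with DE but not with an estimated correlation. S phase had a mean of 0.21 (adjusted p = 2.64e-08, adjusted p = 0.487 with an estimated correlation), with 0 of 39 genes over all genes and 5 adjusted over the list alone. Cholesterol synthesis had a mean of 0.33 (adjusted p = 1.23e-09, adjusted p = 0.293 with an estimated correlation), with 0 of 25 genes and 4 adjusted over the list alone. In the lysosome list 3 genes rose, the cathepsin Ctss (2.12-fold), Gpnmb (2.02-fold) and Scarb2 (1.46-fold), with a list mean of 0.14 (adjusted p = 0.000627, adjusted p = 0.533 with an estimated correlation). Macrophage markers had a mean of 0.26 with 0 of 10 past limma (adjusted p = 0.0471, adjusted p = 0.306 with an estimated correlation). In the collagen list Col5a2 fell 1.65-fold, the list mean was -0.15 (adjusted p = 0.00784, adjusted p = 0.488 with an estimated correlation), and 4 genes fell and 1 rose adjusted over the list alone. Against DMSO in place of water the collagen, lysosome and macrophage calls were lost.

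The test called 327 genes with DE, 181 higher and 146 lower, and 3419 had an unadjusted p under 0.05. On the 8 arrays of both groups alone limma called 0 genes (3102 with an unadjusted p under 0.05), and against DMSO 1002. The count was 87 without water replicate 3, 95 without water replicate 4, 164 without DE replicate 1 and 169 without DE replicate 3. Scaled on the median of the genes it was 27, with 77.8% higher in place of 55.4%. With the slide as a block 461 genes were called, and on slides 1, 2 and 3, with 1, 1 and 2 DE arrays against 1, 2 and 1 water arrays and the spread taken from all arrays, 51, 49 and 61. On those slides the G2 and mitosis mean was 1.22, 0.56 and 0.87 (0.83 with the block), the interferon mean 0.78, 0.54 and 0.83 (0.65 with the block), the proliferin mean 0.58, 1.17 and 0.95 (0.91 with the block) and the NF-kB mean 0.38, 0.41 and 0.65 (0.46 with the block).

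At the same dose, NM-203 and DE differed directly in 9494 genes, 4541 higher and 4953 lower with NM-203. Prl2c3 was 12.6-fold higher with NM-203 (log2 difference 3.66 ± 0.20, limma adjusted p = 4.38e-14), and the lipid transporter Mfsd2a at least 5.97-fold. Slco2b1 was at least 11.9-fold lower, Ptgds 19.0-fold lower and the organic cation transporter Slc22a2 16.2-fold lower. The share of higher calls was 47.8%, and 60.7% when scaled on the median of the genes, where the median difference of all genes was 0.105.

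Min-U-Sil 5, a crystalline silica, was compared at 20 µg/cm² with its own water control. It too raised cell division genes and lowered matrix genes. All 43 G2 and mitosis genes rose (mean 1.60, camera adjusted p = 4.07e-38), Sgo1 by 4.27-fold, and 35 of 39 S phase genes rose (mean 1.45, adjusted p = 2.62e-34), Mcm10 by 5.30-fold. Prl2c3 rose 19.4-fold (log2 change 4.27 ± 0.20, limma adjusted p = 1.26e-15), Car6 17.9-fold, Saa3 15.7-fold (adjusted p = 8.6e-12), the actin-binding villin relative Avil 10.2-fold, and Atp13a4 at least 5.37-fold. Slco2b1 was 20.4-fold lower, Postn 13.0-fold, Sparcl1 12.4-fold and Apobec2 at least 5.18-fold.

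Of 29 collagen and matrix genes 22 fell with Min-U-Sil 5 (mean -0.92, camera adjusted p = 5.65e-17), including Lum (5.29-fold) and tenascin Tnc (3.20-fold). Of 20 metalloproteinase genes 11 fell and 2 rose (mean -0.59, adjusted p = 7.26e-05), including Mmp9 (5.45-fold), and of 28 growth factor genes 11 fell and 3 rose (mean -0.30, adjusted p = 0.00156), including Igf2 (4.36-fold), while Fgf21 was at least 3.64-fold higher. NRF2 antioxidant genes rose, 15 of 33 with 2 lower (mean 0.43, adjusted p = 3.35e-06), led by Slc7a11 (7.08-fold), Gclc (3.19-fold) and the efflux pump Abcc4 (2.14-fold). These lists, both cell cycle lists and the proliferins (mean 4.02, adjusted p = 8.76e-11) held with an estimated correlation.

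Another 7 lists passed camera with Min-U-Sil 5 only at the preset correlation. Of 27 interferon stimulated genes 10 rose (mean 0.38, adjusted p = 0.00156, adjusted p = 0.54 with an estimated correlation), including Oasl1 (3.98-fold) and Rsad2 (2.62-fold). The stress response list rose in 11 of 33 genes (mean 0.47, adjusted p = 7.26e-05, adjusted p = 0.12 with an estimated correlation), including Mthfd2 (3.33-fold). Heat shock genes rose in 10 of 17 and fell in 2 (mean 0.35, adjusted p = 0.00162, adjusted p = 0.194 with an estimated correlation), and ERK output genes rose in 9 of 21 and fell in 3 (mean 0.40, adjusted p = 0.0287, adjusted p = 0.361 with an estimated correlation), including Dusp4 (5.21-fold) and Etv4 (2.63-fold). Adhesion genes fell in 11 of 25 and rose in 3 (mean -0.25, adjusted p = 0.0046, adjusted p = 0.12 with an estimated correlation). Lysosome genes fell in 9 of 39 and rose in 3, Gpnmb by 2.41-fold (mean -0.17, adjusted p = 0.00881, adjusted p = 0.543 with an estimated correlation). The p53 targets fell in 8 of 27 and rose in 3 (mean -0.15, adjusted p = 0.0484, adjusted p = 0.492 with an estimated correlation) and lost the call with the slide as a block (adjusted p = 0.143). Of 25 NF-kB targets, which did not pass (adjusted p = 0.127), 9 rose and 5 fell, and Ptgs2 rose 3.67-fold and complement C3 fell 4.79-fold. Adjusted over the list alone, 25 collagen, 12 growth factor, 13 lysosome, 9 p53, 4 ERK and 1 S phase gene fell, 38 S phase, 3 metalloproteinase and 16 NRF2 genes rose, and the other counts of these lists were unchanged.

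The test called 8302 genes with Min-U-Sil 5, 3773 higher and 4529 lower, and 8746 with the slide as a block. Slide 4, whose arrays of these groups stood apart in the first component, gave 6001 calls from 3 arrays against 2, and slide 5 gave 3220 from 1 array against 2 with the spread taken from all arrays, and without slide 4 the count was 3587. On slides 4 and 5 the G2 and mitosis mean was 1.72 and 1.56 (1.65 with the block), the S phase mean 1.53 and 1.44 (1.49), the proliferin mean 4.08 and 4.11 (4.06) and the collagen mean -0.82 and -1.03 (-0.89).

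The effects of NM-203 at 5 µg/cm² and Min-U-Sil 5 at 20 µg/cm², doses that differ, were compared each against its own control. They differed in 65 genes, 30 with the higher change under NM-203. Among these were interferon-related genes: Ifi205 changed by 2.00 more on the log2 scale under NM-203 (limma adjusted p = 0.0301), Rsad2 by 1.62 (adjusted p = 0.0139), Oas1g by 1.35 and the nucleic acid sensor Zbp1 by 1.33. Fmo2 changed by -2.21 relative to Min-U-Sil 5 (adjusted p = 0.024) and the muscle cadherin Cdh15 by -1.66. All 8 genes selected for naming from those eligible here kept their direction. They fell short of the threshold without slide 4, on the arrays of these groups alone and when scaled on the median of the genes. With quantile scaling 7 of them also fell short. The count was 17 to 182 when 1 array was left out. It was 19 and 28 without water replicates 3 and 4, 42, 19 and 155 without NM-203 replicates 1, 3 and 4, 17, 33 and 34 without Min-U-Sil 5 water replicates 1, 2 and 4, and 17, 182 and 20 without Min-U-Sil 5 replicates 1, 3 and 4. The higher share was 46.2%, 68.6% of 35 calls with normexp and 0 of 3 calls scaled on the median of the genes, and 91 genes were called with the slide as a block.

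DE at 5 µg/cm² and Min-U-Sil 5 at 20 µg/cm² differed in effect in 3421 genes, 1600 with the higher change under DE. Prl2c3 changed by -3.34 ± 0.28 under DE relative to Min-U-Sil 5 (limma adjusted p = 5.45e-09), with Prl2c1 at -2.97 and Prl2c5 at -2.98. Slco2b1, the transcription factor gene Spib and Ptgds changed by 3.78, 3.54 and 3.01 in the other direction. The count was 1393 without slide 4 and 1003 scaled on the median of the genes. The balance turned to 1978 higher and 1847 lower under DE with quantile scaling and to 1810 and 1646 with normexp, so these directions are relative to the scaling.

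TPA, a phorbol ester that acts as a tumour promoter, was compared with DMSO. All 43 G2 and mitosis genes rose (mean 2.11, camera adjusted p = 1.43e-93) and 34 of 39 S phase genes rose, 36 with 1 lower adjusted over the list alone (mean 1.17, adjusted p = 1.5e-47), with Nusap1 at 5.75-fold, cyclin Ccna2 at 5.65-fold, Cdc45 at 4.12-fold and Tk1 at 4.07-fold. Prl2c3 rose 17.5-fold (log2 change 4.13 ± 0.20, limma adjusted p = 4.44e-15), Nlrp2 10.2-fold and the mitotic kinesin Kif18b 7.90-fold (adjusted p = 0.000788). Timp4, an inhibitor of metalloproteinases, fell 15.7-fold and Postn 15.5-fold. The cell cycle lists and the proliferins (mean 3.71, adjusted p = 1.24e-17) held with an estimated correlation.

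The other 6 lists past camera with TPA did not hold with an estimated correlation. Interferon stimulated genes rose in 14 of 27, 21 adjusted over the list alone (mean 0.55, adjusted p = 1.13e-14, adjusted p = 0.112 with an estimated correlation), including Zbp1 (2.54-fold). Cholesterol synthesis genes rose in 8 of 25 and fell in 1, 15 and 1 adjusted over the list alone (mean 0.45, adjusted p = 1.57e-07, adjusted p = 0.305 with an estimated correlation), including Nsdhl (2.05-fold). NF-kB targets rose in 6 of 25 and fell in 1, 7 and 1 adjusted over the list alone (mean 0.30, adjusted p = 0.0152, adjusted p = 0.305 with an estimated correlation), including Saa3 (3.84-fold, adjusted p = 5.76e-06) and Ccl8 (2.92-fold). Collagen and matrix genes fell in 15 of 29 and rose in 2, 17 and 4 adjusted over the list alone (mean -0.53, adjusted p = 1.08e-07, adjusted p = 0.0872 with an estimated correlation), including Lum (4.28-fold) and thrombospondin Thbs1 (2.41-fold). Lysosome genes fell in 10 of 39, 14 lower and 1 higher adjusted over the list alone (mean -0.26, adjusted p = 3.92e-05, adjusted p = 0.305 with an estimated correlation), including Neu1 (1.62-fold), and smooth muscle genes fell in 6 of 18, 7 adjusted over the list alone (mean -0.32, adjusted p = 0.00312, adjusted p = 0.243 with an estimated correlation), including Ccn1 (2.85-fold) and Myl9 (2.06-fold). Of 24 AP-1 and immediate early genes, a list that did not pass (adjusted p = 0.0913), 4 rose and 8 fell, with falls of Nr4a1 (5.71-fold), Egr1 (3.96-fold) and Fos (3.71-fold). The mean level of this list was scattered in both groups, 0.42 (SD 0.32) in DMSO and 0.0091 (SD 0.33) in TPA, beside 0.21 (SD 0.061) in water. As limma took the spread from all groups, it can understate the error of these falls. The metalloproteinase list did not pass (adjusted p = 0.686), with 4 of 20 genes lower, Mmp9 by 1.56-fold, and 1 higher.

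The test called 3792 genes with TPA, 1589 higher and 2203 lower, 3155 with the slide as a block and 459 on slide 1, the 1 slide that held both groups, with 2 TPA arrays against 1 DMSO array and the spread taken from all arrays. On slide 1 the G2 and mitosis mean was 1.86 (2.31 with the block), the S phase mean 1.12 (1.27), the proliferin mean 3.49 (3.66) and the interferon mean 0.32 (0.73). The share of higher calls was 41.9%, and 55.6% when scaled on the median of the genes.

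Against TPA, the effect of NM-203 at 5 µg/cm² differed in 4807 genes, 2514 with the higher change under NM-203 and 2293 with the lower. With quantile scaling the balance turned to 1982 higher and 2240 lower, and scaled on the median of the genes 1983 were called, 1096 higher and 887 lower. Car6 changed by 3.22 ± 0.30 more under NM-203 (limma adjusted p = 4.14e-08), Saa3 by 2.98 and Ccn1, a matrix protein gene, by 2.89, while transglutaminase Tgm2 changed by -3.60 and Ces1f by -3.25. Min-U-Sil 5 and TPA differed in effect in 1915 genes, 56.6% with the higher change under Min-U-Sil 5, and in 429 with 45.7% higher when scaled on the median of the genes. Car6 changed by 3.19 more under Min-U-Sil 5 and the glutathione transferase Gsta2 by 2.81, while Chil1 changed by -3.03 and Tgm2 by -2.88. Without slide 4 the count was 552.

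**Figure D4:**
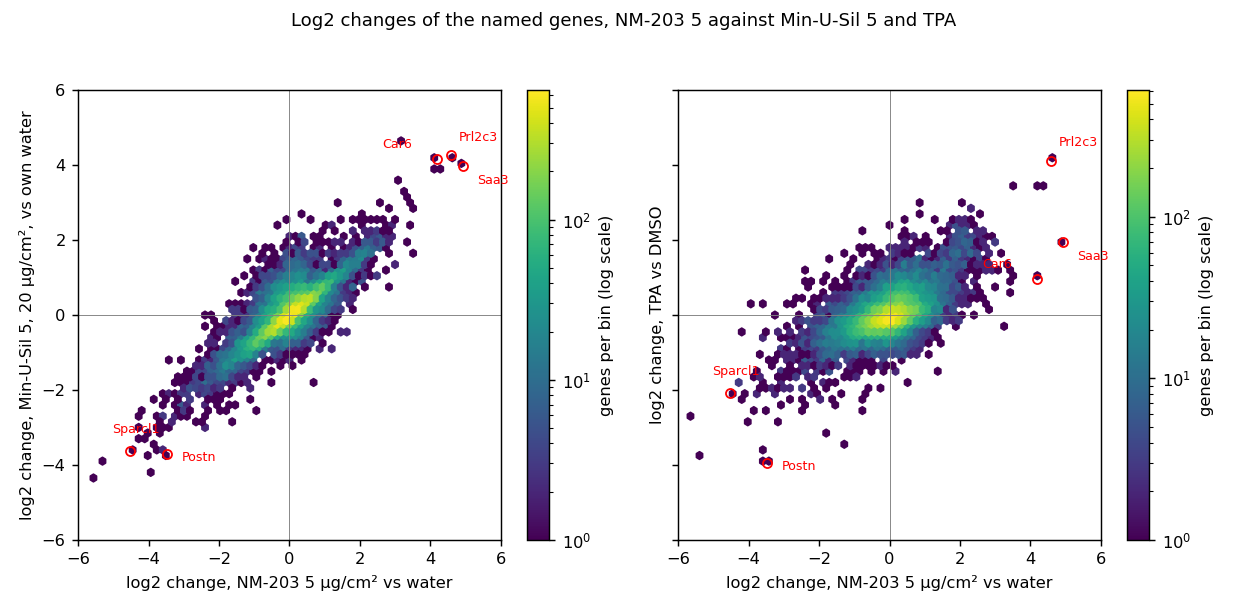
Log2 changes of 17868 named genes under NM-203 at 5 µg/cm² against those under Min-U-Sil 5 (left) and TPA (right), each against its own control, with the number of genes per bin on a log colour scale. Across genes r was 0.822 for Min-U-Sil 5 and 0.588 for TPA, and Car6 lay at 4.19 under NM-203 and 4.16 under Min-U-Sil 5.

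The changes of the different treatments were then set against each other. NM-203 at 5 µg/cm² and Min-U-Sil 5, which have separate controls, shared 3169 higher and 4028 lower genes, against 528 and 863 for independent lists, and 1 gene was called in opposite directions. Across the 32489 genes, which are not independent replicates, their log2 changes correlated with r = 0.762 (Spearman 0.707). NM-203 at 5 µg/cm² and TPA shared 1185 higher and 1604 lower genes, against 222 and 420 for independent lists, with 131 in opposite directions (r = 0.559), and Min-U-Sil 5 and TPA shared 1114 and 1515, against 185 and 307, with 76 opposite (r = 0.537). Scaled on the median of the genes, the balance turned to 723 higher and 584 lower for the former pair and 622 and 560 for the latter. The 3 treatments together shared 1070 higher and 1426 lower genes, against 25.8 and 58.5 for independent lists.

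NM-203 at 5 µg/cm² and DE share the water arrays. They shared 156 higher and 124 lower genes, against 25.3 and 27.8 for independent lists, 85.6% of all DE calls, with 4 in opposite directions. Their changes correlated with r = 0.477 (covariance 0.112). Simulated unchanged groups with a shared control, drawn from all arrays and not from the water arrays alone, gave a mean r of 0.452 (-0.0415 to 0.780 over 100 draws). The mean simulated covariance was 0.0466 (-0.00322 to 0.127), so both observed values lay within the simulated range. Noisier groups entered these draws (median SD 0.376 for NM-203 at 2 µg/cm² against 0.213 for water), so the range is not that of the water arrays. With the water arrays split between both comparisons the mean r was 0.252 and the mean covariance 0.0710. Over the 6 splits the shared genes ran from 4 to 208 higher and from 0 to 68 lower. The counts for independent lists take no account of the shared water arrays, so they do not give the overlap due to chance. The shared count was 79 and 88 without water replicates 3 and 4, 146 and 152 without DE replicates 1 and 3, and 0 when limma was fitted on the arrays of each comparison alone, where DE had 0 calls (3102 with an unadjusted p under 0.05). DE calls overlapped with TPA calls, which have their own DMSO control, in 140 higher and 96 lower genes, against 8.85 and 9.90 for independent lists, with 1 opposite.

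The controls were compared with each other to measure the background. DMSO and water differed in 0 genes by limma, with 673 at an unadjusted p under 0.05. The Min-U-Sil 5 water control differed from the other water control in 7948 genes, 6106 higher and 1842 lower, with a median change of 0.22 over all genes. The higher share was 76.8%, and 58.6% with quantile scaling, 61.1% with normexp and 35.0% scaled on the median of the genes. These groups were scanned on different days, and 81 genes were called with the scan day as a block and 78 with the slide. The count was 4468 without water replicate 1, and 4559 and 4632 without Min-U-Sil 5 water replicates 2 and 3.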

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

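The tests of the G2 and mitosis list and of the interferon list were set before their results were seen, and the tests of the difference between water controls and the counts over other splits of the arrays were chosen after the results were seen.

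The Min-U-Sil 5 water control differed from the other water control in 7948 genes, the pattern weighed first. Probes near background stay open as a cause for the 6106 higher genes, of which 43.2% were brighter than the median of the genes tested. Among all calls of each treatment against its control this share was 72.6% to 82.1%. Dim genes were thus more frequent among these 6106 genes than among those calls, which hold both directions. Brightness was the mean over all 36 arrays, and a probe could pass the filter through 1 group alone. Genes bright mainly in the Min-U-Sil 5 water control can therefore count as dim, so part of this difference may come from the filter. For the 1842 lower genes 87.1% were brighter, which argues against it. Scan day and slide cannot be told apart from the groups: the second-day arrays of NM-203 at 1 and 5 µg/cm² deviated from their first-day arrays in the direction of the control difference by medians of 0.125 and 0.0958, against a median absolute difference of 0.75 between controls. Both of those second-day arrays were on slide 5. They cannot speak for slide 4, which held replicates 2 and 3 of the Min-U-Sil 5 water control. With the slide as a block the median absolute difference of these genes was 0.477 with a median SE of 0.285, in place of 0.75 with 0.198, and 96.7% kept their direction, so the calls ended through a smaller difference and a larger error. No biological explanation was tested, and a separate preparation of the cells stays open.

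G2 and mitosis genes were higher than in water after both mild treatments, NM-203 at 1 µg/cm² and DE. Against a chance low level of the shared water arrays, the list was also higher than in DMSO on first-day arrays, by 0.985 (95% CI 0.588 to 1.38) for NM-203 and 0.879 (0.511 to 1.25) for DE. DMSO was the lowest control, however, with a mean level of -0.346 beside -0.216 in water. The Min-U-Sil 5 water control, scanned on the second day, lay at 0.142, nearer to NM-203 (0.553) and DE (0.533). A low level of the water arrays therefore stays open as a cause of part of the difference. Against slide and scan day, the differences from water with the slide as a block were 0.872 (0.517 to 1.23) and 0.831 (0.487 to 1.18), beside 0.769 and 0.749 without it. An effect of the treatments themselves remains as a hypothesis, and the share of dividing cells was not measured here.

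Interferon stimulated genes changed more under NM-203 at 5 µg/cm² than under Min-U-Sil 5, by 0.853 (95% CI 0.534 to 1.17). With the slide as a block the difference was 0.920 (0.612 to 1.23), which argues only against additive shifts between slides. Such shifts largely cancel here, as all water arrays and 3 of 4 NM-203 arrays were scanned on the first day. All Min-U-Sil 5 arrays and their water control were scanned on the second. A response that differs between scan days could not be separated from the treatments. A higher starting level in the Min-U-Sil 5 water control stays open: with the scan day as a block it was higher than the other water control by 0.434 (95% CI 0.0839 to 0.784), a range that includes both a small and a large part of the difference. The level reached was 3.94 under NM-203 and 3.57 under Min-U-Sil 5. The different dose and form of silica may also matter and could not be separated in this design.

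Splits of the arrays into other groups of the same sizes show how often another grouping gives as large a result. The real split is counted among them, so the smallest possible share is 1 of 35, or 1 of 100 where splits were drawn. No adjustment was made over the comparisons. These fits filled spots left out with the mean of their group, so real counts can differ by a few genes from those on the same arrays elsewhere. For counts of genes, fitted on the 8 arrays alone, the real split was the only 1 of 35 with so many calls for NM-203 at 2 µg/cm² (2918, highest other 0), NM-203 at 5 µg/cm² (10658, highest other 0), Min-U-Sil 5 (6923, highest other 127, a split with all 3 slide 5 arrays on one side), TPA (2883, highest other 5), NM-203 against DE (7288, highest other 0) and the water controls (3114, highest other 0). The other splits thus did not give such counts there, although scan day cannot be excluded for NM-203 at 2 µg/cm² and the water controls. For NM-203 at 1 µg/cm², DE, and DMSO against water the real count by limma on 8 arrays was 0, so 35 of 35 splits gave as many by construction and the splits decide nothing (highest others 7, 11 and 9); these comparisons had 2673, 3102 and 1198 genes with an unadjusted p under 0.05. For the dose slope the real assignment of arrays to doses was the only 1 of 100 with so many calls (10391, highest other 43). For differences between effects 2 of 100 gave as many for NM-203 and TPA (5198, highest other 6362), 4 for DE and Min-U-Sil 5 (3225, highest other 4766) and 4 for Min-U-Sil 5 and TPA (1943, highest other 13531), and 7 for NM-203 and Min-U-Sil 5 (1, highest other 6013). Draws with several times the real count point to a structure of the samples: they exchange arrays between treatments, and between controls, that can differ themselves, so they do not decide whether chance gives these differences.

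For lists past camera on the 8 arrays, the real split was the only 1 of 35 with as many for NM-203 at 5 µg/cm² (13, highest other 12). Chance cannot be excluded for the number of lists with NM-203 at 1 µg/cm² (11, 3 of 35 splits, highest other 12), NM-203 at 2 µg/cm² (9, 11 splits, highest other 14), DE (9, 5 splits, highest other 10), Min-U-Sil 5 (15, 7 splits, highest other 20) and TPA (8, 6 splits, highest other 12).

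Some single arrays lay far from the other 3 of their group, measured by the gap to the nearest array over the group's range and Dixon's 95% critical value, which chance passes in about 1 in 20 groups. This was so in 28 of 496 tests of named genes, 12 of 252 tests of lists and 1 of 18 tests of array measures, with at most 3 on any array. In NM-203 at 1 µg/cm² these were Aspm in replicate 1 (0.848), Tmem158 in replicate 3 (0.896), the heat shock (0.831) and TGF-beta (0.854) lists in replicate 4, and the number of probes well above background in replicate 2 (0.944, 36064 against a mean of 34237). In NM-203 at 2 µg/cm² they were Plk1 (0.908), the cholesterol list (0.830) and the epithelial markers (0.971) in replicate 1, and Car6 (0.848), Casp1 (0.856) and Oasl1 (0.849) in replicate 4. In NM-203 at 5 µg/cm² they were Cdh5 in replicate 1 (0.917), the endothelial markers in replicate 2 (0.898), Cacna1g (0.841), Ifi205 (0.844) and the scavenger receptors (0.846) in replicate 3, and Hbegf (0.887), Mmp9 (0.835) and Ncam1 (0.855) in replicate 4. In water they were Kif4 (0.960), Ccrl2 (0.867) and the macrophage markers (0.866) in replicate 1, Aox1 (0.835) and Nlrp2 (0.923) in replicate 2 and Ifi213 in replicate 4 (0.934). In DE they were Lcn2 (0.834) and the epithelial markers (0.831) in replicate 3 and the adipocyte markers in replicate 4 (0.849). In Min-U-Sil 5 they were Ncam1 (0.956), Ptgs2 (0.888) and Gsta2 (0.835) in replicate 2, Fmo2 (0.913), the AP-1 list (0.866) and the macrophage markers (0.874) in replicate 3, and Psat1 (0.949) and Serpinb9g (0.837) in replicate 4, and in its water control Ptgs2 in replicate 1 (0.831). In DMSO they were Ereg (0.842) and Nusap1 (0.896) in replicate 1 and Thbs1 in replicate 4 (0.899), and in TPA the endothelial markers in replicate 3 (0.876).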

How the results depend on the processing

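The fits on the first scan day, with DMSO or the second water group as a control, without slide 4 and with the value table's numbering were chosen after the data were seen; the other alternatives were planned. Of the named genes' results under the alternatives, 4638 kept their direction and side of the threshold, 287 kept the direction and fell short of it, 2 came past it and 1 was reversed, and with 1 array left out 2231 were kept and 173 fell short. Of the lists' results 2856 were kept, 101 came past the threshold and 91 fell short. Another 109 changed direction without passing the threshold in either fit, and 1 was reversed, which means that it changed direction and passed in at least 1 fit. With 1 array left out 1226 were kept, 40 came past, 26 fell short and 52 changed direction without passing in either fit. The reversed ones were Txnrd1 after NM-203 at 2 µg/cm² (0.0259 against the second water group, 2.00-fold lower against water) and the lysosome list after NM-203 at 1 µg/cm² (-0.0308 against DMSO, 0.0841 against water). Where no reason is given below, the cause was not tested.

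NM-203 at 1 µg/cm² changed 28 genes, and 1 with median scaling, 16 with the deposited table, 5 with no filter, 56 with probes well above background on all 36 arrays, 15 with the mean of probes, 48 with every probe on its own, 0 on its own arrays, 100 with the slide block, 52 with trended robust variances, 305 with array weights, 6 at least 2-fold, 4 on the first scan day (fewer arrays, not tested as the cause) and 105 against DMSO. NM-203 at 2 µg/cm² changed 8125 genes, and 5334 with median scaling, 2912 on its own arrays, 2327 with the slide block, 1716 with the scan block, 4540 at least 1.5-fold, 2046 at least 2-fold and 1692 against the second water group. With the scan and slide blocks the median absolute change of its called genes went from 0.634 to 0.533 and 0.543 and the median SE from 0.145 to 0.218 and 0.216. NM-203 at 5 µg/cm² changed 10740 genes, and 3656 at least 2-fold. DE changed 327 genes, and 27 with median scaling, 209 with no filter, 0 on its own arrays, 577 with array weights, 213 at least 1.5-fold, 66 at least 2-fold and 1002 against DMSO. Min-U-Sil 5 changed 8302 genes, and 4976 at least 1.5-fold, 2063 at least 2-fold and 3587 without slide 4 (fewer arrays, not tested as the cause). TPA changed 3792 genes, and 1746 with median scaling, 6443 with array weights, 2029 at least 1.5-fold and 900 at least 2-fold. The slope with dose had 11286 genes, and 101 at least 1.5-fold and 2 at least 2-fold per µg/cm². NM-203 against DE had 9494 genes, and 6046 at least 1.5-fold and 2693 at least 2-fold.

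Effects of NM-203 and TPA differed in 4807 genes, and 1983 with median scaling and 1537 at least 2-fold. Those of NM-203 and Min-U-Sil 5 differed in 65, and 18 with quantile scaling, 3 with median scaling, 35 with normexp, 1 on their own arrays, 1138 with array weights and 29 without slide 4. Those of DE and Min-U-Sil 5 differed in 3421, and 1003 with median scaling, 1047 at least 2-fold and 1393 without slide 4. Those of Min-U-Sil 5 and TPA differed in 1915, and 429 with median scaling, 4170 with array weights, 557 at least 2-fold and 552 without slide 4. The water controls differed in 7948 genes, and 3108 on their own arrays, 78 with the slide block, 81 with the scan block, 15745 with array weights, 4920 at least 1.5-fold, 3026 at least 2-fold and 2677 without slide 4. DMSO and water differed in 0 genes by limma (673 at an unadjusted p under 0.05), and 1 with quantile scaling, 1 with probes well above background on all 36 arrays and 2 with array weights.

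Lists past the threshold were 9 after NM-203 at 1 µg/cm² (3 with an estimated correlation, 5 by fry), 8 at 2 µg/cm² (14 with no filter, 0 with an estimated correlation, 16 by fry), 14 at 5 µg/cm² (9 with an estimated correlation), 9 with DE (4 with an estimated correlation, 5 by fry), 14 with Min-U-Sil 5 (7 with an estimated correlation) and 9 with TPA (3 with an estimated correlation, 15 by fry). For the 0 lists at 2 µg/cm², 7 had an unadjusted p under 0.05. NM-203 at 5 µg/cm² and Min-U-Sil 5 shared 7197 genes, and 4696 with median scaling, 4216 at least 1.5-fold and 1614 at least 2-fold. NM-203 and TPA shared 2789, and 1307 with median scaling, 4208 with array weights, 1498 at least 1.5-fold and 672 at least 2-fold. Min-U-Sil 5 and TPA shared 2629, and 1182 with median scaling, 3994 with array weights, 1349 at least 1.5-fold and 563 at least 2-fold. NM-203 and DE shared 280, and 26 with median scaling, 182 with no filter, 0 on their own arrays, 504 with array weights, 185 at least 1.5-fold, 54 at least 2-fold and 770 against DMSO.

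With each array left out in turn, the count ran from 2 to 101 genes for NM-203 at 1 µg/cm² (lowest without water replicates 3 or 4 or NM-203 replicate 2, highest without water replicate 1), 6755 to 8176 at 2 µg/cm², 9589 to 10650 at 5 µg/cm², 87 to 367 for DE (lowest without water replicate 3), 7056 to 8140 for Min-U-Sil 5, 2844 to 3984 for TPA, 9976 to 11207 for the slope and 8361 to 9444 for NM-203 against DE. It ran from 4077 to 5224 for NM-203 and TPA, 17 to 182 for NM-203 and Min-U-Sil 5 (highest without Min-U-Sil 5 replicate 3), 2890 to 3338 for DE and Min-U-Sil 5, 1467 to 1914 for Min-U-Sil 5 and TPA, 4468 to 9450 for the water controls (lowest without water replicate 1) and 0 to 0 for DMSO and water. Lists past camera ran from 8 to 11 and 8 to 12 at 1 and 2 µg/cm² of NM-203, 13 to 14 at 5 µg/cm², 7 to 12 for DE, 13 to 14 for Min-U-Sil 5 and 9 to 10 for TPA. Shared genes ran from 6486 to 7104 for NM-203 and Min-U-Sil 5, 2120 to 2761 for NM-203 and TPA, 2055 to 2583 for Min-U-Sil 5 and TPA and 79 to 324 for NM-203 and DE.

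With the replicate number as a block, 34, 7304, 10279, 223, 7773 and 3331 genes were called for NM-203 at 1, 2 and 5 µg/cm², DE, Min-U-Sil 5 and TPA, 8175 for Min-U-Sil 5 with the value table's numbering, and 10 for NM-203 and Min-U-Sil 5 in place of 65. After removal of group means, 1, 1, 0, 1, 1 and 2 of 4 pairs with the same number correlated above 0.1, and 2, 1, 0, 1, 1 and 2 treated arrays correlated best with their own number, so the numbers were not taken to pair the arrays. Signal over background limits the dim genes: 31189 to 43117 probes per array were well above it.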

Other observations

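The tests of gene families by name and the permutation of list levels were chosen after the data were seen.

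Gene families taken by the root of their symbol, with at least 8 members tested, were tested beside the fixed lists, with which the Col and Mcm families share members. After NM-203 at 5 µg/cm², 15 of 18 clustered beta-protocadherins (Pcdhb), cell adhesion proteins, fell with a mean log2 change of -1.31 (camera adjusted p = 8.32e-11 over 293 families), although near-identical members can share signal, so the number of separate genes is uncertain. Of 36 Ddx RNA helicases 20 rose and 1 fell (mean 0.54), of 10 Exosc genes of the RNA exosome 8 rose (mean 0.88), of 8 nucleolar Nop genes 6 rose (mean 0.98), of 18 Rad genes, many of them for DNA repair, 10 rose and 2 fell (mean 0.79), and of 15 tetraspanins (Tspan) 8 fell (mean -0.58). The collagens (Col) fell in 21 of 37 (mean -0.89). Each of these 7 families also passed with an estimated correlation (adjusted p = 0.0366).

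With Min-U-Sil 5 the same 7 families passed with both settings, in the same directions: Pcdhb in 13 lower (mean -0.78), Exosc in 8 higher (mean 0.66), Ddx in 16 higher (mean 0.43), Nop in 6 higher (mean 0.76), Rad in 11 higher (mean 0.54), Tspan in 7 lower (mean -0.35) and Col in 20 lower (mean -0.57). Of 10 genes with the root Hoxa, 9 of them for developmental transcription factors and 1 for an antisense RNA, 5 fell (mean -0.65). With TPA the Mcm genes, most of them of the replicative helicase, rose in 8 of 10 (mean 1.17) and Rad genes in 7 (mean 0.56), and Pcdhb fell in 10 with a mean of -0.47 (adjusted p = 1.1e-05, adjusted p = 0.172 with an estimated correlation). Mcm and Hoxa were not particular to these treatments. Mcm genes rose in 9 of 10 after NM-203 at 5 µg/cm² and with Min-U-Sil 5. Hoxa genes fell in 5 of 10 after NM-203 at 5 µg/cm². There camera passed them only at the preset correlation (adjusted p = 0.0811, 0.0544 and 0.1 with an estimated one). In NM-203 at 1 and 2 µg/cm² and in DE 0 families passed with an estimated correlation, and 21, 28 and 17 passed with the preset one. The means given here for NM-203 at 5 µg/cm², Min-U-Sil 5 and TPA kept their sign under quantile, median, normexp and deposited scaling. With normexp the Pcdhb mean was -0.80 after NM-203 at 5 µg/cm² and the Hoxa mean -0.39 with Min-U-Sil 5. With median scaling the Tspan falls were 5 after NM-203 and 4 with Min-U-Sil 5, the Ddx rises with Min-U-Sil 5 were 10 and the Pcdhb falls with TPA were 6.

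The mean level of each list per array was also compared between groups by an exact two-sided permutation over the 70 arrangements of 8 arrays, whose smallest possible p is 0.0286. The groups separated fully for 6, 14 and 18 of 28 lists at 1, 2 and 5 µg/cm² of NM-203, 5 with DE, 17 with Min-U-Sil 5 and 11 with TPA. The smallest adjusted p was 0.133, 0.0571, 0.0444, 0.16, 0.0471 and 0.0727 in that order.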
